A study of Arabidopsis thaliana with 6 samples.

How the data were processed

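Whole-genome bisulfite sequencing measured DNA methylation in 6 libraries of Arabidopsis thaliana, 3 of the wild-type accession Col-0 and 3 of rbp-ko-1, a mutant of the RNA-binding protein gene RBP45D (AT5G19350), also called KO27. Plants were 26 days old and grown with 16 h of light and 8 h of dark. Per the labels' protocols, DNA was extracted with a Qiagen DNeasy kit, treated with the EZ DNA Methylation-Gold kit and amplified with KAPA HiFi Uracil+ polymerase. Bisulfite turns unmethylated cytosine into uracil, which is read as thymine, while methylated cytosine stays cytosine. An unmethylated cytosine that escapes conversion is therefore read as methylated, and this weighs most on CHH, where true levels are lowest. Conversion rates are not given in the sources used here.

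Per the submitters' processing notes, Trimmomatic, FastQC, Bismark and MethylDackel were used with genome build TAIR10, and no versions are named. The program that called the differentially methylated regions (DMRs), its thresholds, the gene annotation and the length of a promoter are not given in the sources used here. The file analysed is the authors' table of DMRs between rbp-ko-1 and Col-0, with 1 entry per DMR and annotated gene. It held 18828 entries for 9213 DMRs, of which 4620 had more than 1 entry. Each was called in 1 of 3 sequence contexts, CG, CHG or CHH, where H is A, C or T. The methylation level of each DMR was deposited by the authors as a fraction, 1 mean per genotype over its libraries, and is given here in percent. The difference is the rbp-ko-1 mean minus the Col-0 mean, in percentage points. The area statistic is a score deposited by the authors, signed as the difference and larger in size for longer regions and clearer differences. It was used only to rank DMRs within a context. In 1 DMR the difference and the area statistic had opposite signs, and the difference was used.

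The table held no values per library, no read counts and no coverage, so the depth behind each level is unknown and no level carries an SD, an n or an interval. The planned test per library was therefore not run. Nothing in the labels says whether the 3 libraries of a genotype came from separate plants or pools of plants. The p-values below are computed over DMRs or genes, which are not replicates. They describe the deposited list and say nothing about the spread between plants. The smallest absolute difference in the table was 0.817 points in CG, 1.95 in CHG and 0.998 in CHH, and the smallest DMR had 4 cytosines. A gene with no DMR is a gene with no entry in the table, which does not show that its methylation was equal. Every entry had a gene annotation, so DMRs away from annotated genes are not analysed here. No DMR lay in the chloroplast genome.

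DMRs were counted once per context and direction. Lower against higher DMRs were compared with two-sided exact binomial tests, with exact Clopper-Pearson 95% intervals for the share of lower DMRs that cover counting error only. Sizes of difference were compared with two-sided permutation tests of medians (100000 resamples). Annotated features, taken from the authors' table, and the share within 3 Mb of the centromere (taken as 15, 3.6, 14, 4.0 and 12 Mb on chromosomes 1 to 5) were compared between lower and higher DMRs with two-sided Fisher exact tests. Odds ratios above 1 mean more common among higher DMRs. Gene lists fixed in advance, 6 with 129 entries in all, covered flowering time, RNA-directed DNA methylation, maintenance and removal of methylation, the RBP45 and RBP47 family with the U1 snRNP, heat response, and silenced or imprinted genes. Their share of genes with a DMR in the gene or promoter was compared with that of all other protein-coding genes among 27444, by two-sided Fisher exact tests. Overlap between contexts was set against 100 random placements of the DMRs on the same chromosome. The number of DMRs near RBP45D was ranked among windows of 2.0 Mb stepped by 500 kb. All adjusted p-values are Benjamini-Hochberg values within a family of tests (contexts, features by contexts, or the 6 lists within a context), at a threshold of 0.05.

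The lists, tests, named-gene rule and first set of alternatives were chosen before the data were examined. The rule took, for each context and direction, the 4 genes with the largest absolute difference among DMRs of at least 10 cytosines in a gene or promoter, plus each list gene with a DMR and RBP45D. Gene names came from the table and from a RefSeq gene table of assembly TAIR10.1, which matched 6998 of 7699 gene IDs. The RefSeq table also gave gene types, gene lengths, neighbours and the set of all protein-coding genes used in the list tests. Coordinates are those of the deposited table, on TAIR10. Alternatives were a minimum difference of 20 or 30 points, at least 10 cytosines, at least 100 bp, the 50% of DMRs with the larger area statistic, merging within 100 bp, total length, a mean weighted by length, 2 Mb from the centromere, gene bodies only, 500 kb around RBP45D, and an overlap of 50% of the smaller DMR. After the data were seen, a run without the mitochondrial genome and chromosome 2 from 3.2 to 3.6 Mb, which holds a copy of it, was added, as were 10000 random gene lists matched on gene length in 20 bins.

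Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The list test was tested on simulated data with lists of 30 genes among 27444. With a true odds ratio of 3 the median estimate was 2.86 and 77 of 100 lists passed an unadjusted p of 0.05, and with a true ratio of 1, 3 of 100 passed. These runs used the share of genes with a DMR in all contexts together. Smaller lists, single contexts and adjusted p-values were not simulated, so the 77 of 100 does not describe them. The overlap step, run on 2755 simulated regions, returned 31.8% where 30% had been placed on other regions and 2.65% where 0% had been.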

Results

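The data were the authors' DMRs between rbp-ko-1 and Col-0, each with 1 mean methylation level per genotype over 3 libraries. RBP45D encodes an RNA-binding protein of the RBP45 and RBP47 family. The series title places it in flowering under heat and in RNA-directed DNA methylation, the pathway in which small RNAs guide methylation to matching DNA, so the comparison asks where methylation differs without it. In plants, CG methylation is common in gene bodies and transposons, while CHG and CHH methylation mark mainly transposons and repeats. The table gives no spread between libraries and no depth, so whether any single difference exceeds the replicate error could not be tested here. As rbp-ko-1 was the only mutant line, traits of that line cannot be told apart from effects of the mutation.

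Methylation was lower in rbp-ko-1 at most DMRs of all 3 contexts, and CHH regions made up the bulk of the list. Of 9213 DMRs, 8273 were lower and 940 higher in rbp-ko-1. In CHH, 5680 DMRs were lower and 154 higher, so that 97.4% were lower (exact 95% interval 96.9 to 97.8%). In CG, 2174 were lower and 735 higher, a share of 74.7% (73.1 to 76.3%). CHG had the fewest DMRs, 419 lower and 51 higher, a share of 89.1% (86.0 to 91.8%). The exact binomial tests gave adjusted p = 1.99e-163 in CG and 5.45e-73 in CHG, and in CHH a p too small to be represented. At a minimum difference of 30 points CHG had 12 lower and 8 higher DMRs and the call was lost (adjusted exact p = 0.755), and CHH had 1 of each.

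**Figure D1:**
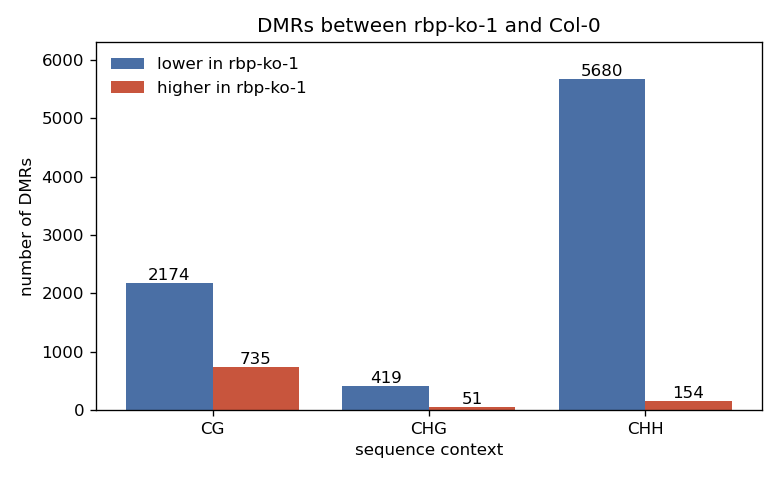
Number of DMRs (vertical axis) in each sequence context (horizontal axis), with blue bars for DMRs lower and red bars for DMRs higher in rbp-ko-1 than in Col-0. The tallest bar is lower CHH with 5680 DMRs, against 154 higher ones.

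At the median lower CHH region, methylation stood at 8.99% in Col-0 and 3.14% in rbp-ko-1. These regions had a median length of 240 bp, and the median ratio of rbp-ko-1 to Col-0 was 0.354, with quartiles of 0.273 and 0.428. Lower CG regions had medians of 29.99% in Col-0 and 7.88% in rbp-ko-1 and a median length of 101 bp, and lower CHG regions had 25.7% and 10.7% over 119 bp. Without the mitochondrial genome and its chromosome 2 copy, the 270 lower CHG regions left had medians of 41.3% and 23.2%, and the lower CG regions 30.5% and 5.32%. In the authors' deposited table the median difference was -5.82 points in CHH, -18.3 in CG and -13.4 in CHG. Among higher regions the medians went from 31.5% to 63.0% in CG, from 8.05% to 24.4% in CHG and from 3.36% to 11.4% in CHH. The median absolute difference was larger in higher than in lower DMRs by 4.67 points in CG (permutation test, adjusted p = 3e-05). The unadjusted permutation p there was 1e-05, the smallest the permutations can give. In CHH higher DMRs were ahead by 0.789 points (permutation test, adjusted p = 0.0105), but not detectably in CHG (2.01 points, adjusted p = 0.162). The CHH difference lost its call among DMRs of at least 10 cytosines (adjusted permutation p = 0.0509) and was 0.130 points between means weighted by length, and the CHG difference turned to -0.80 points without the mitochondrial genome and its chromosome 2 copy (adjusted p = 0.566).

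**Figure D2:**
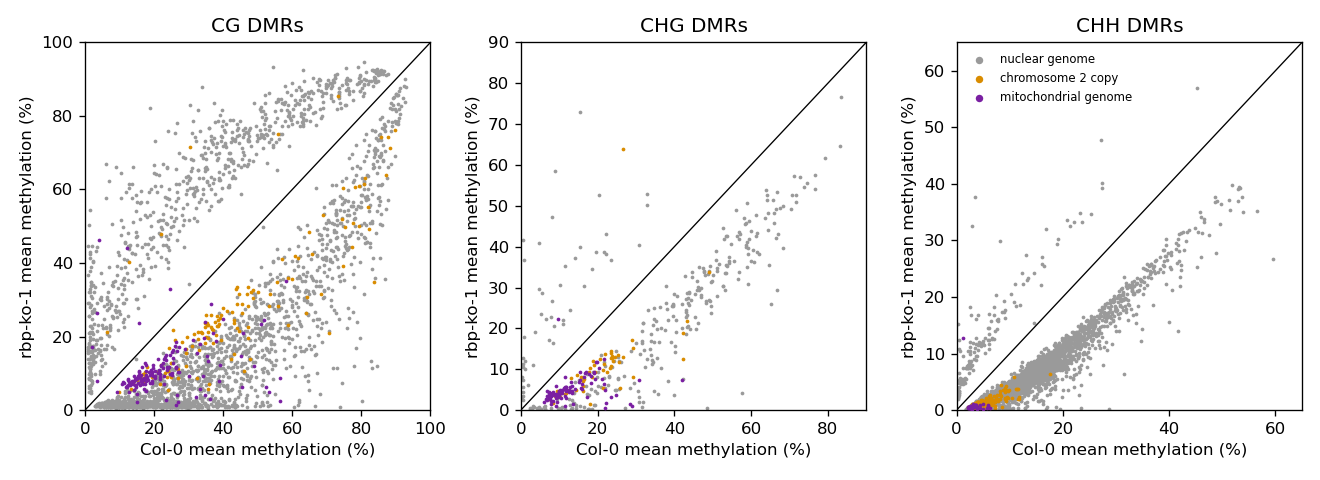
Mean methylation level (%) in rbp-ko-1 (vertical axes) against that in Col-0 (horizontal axes), with 1 point per DMR and 1 panel per context, on axes of different range. Grey points lie in the nuclear genome, orange points in the copy of the mitochondrial genome on chromosome 2 and purple points in the mitochondrial genome, and the black line marks equal levels. Points below the line are lower in rbp-ko-1, as were 5680 of 5834 CHH DMRs.

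The largest single losses named by the fixed rule lay mostly in promoters. In CG, AT4G04601 had 80.3% in Col-0 and 2.45% in rbp-ko-1 at its promoter (chromosome 4, 2311254 to 2311519). At the promoter of YSL2 (AT5G24380), a metal-nicotianamine transporter, the levels were 83.0% and 11.4% (chromosome 5, 8322515 to 8322582). The promoters of RDL3 (AT3G43960), a cysteine protease gene, and AT2G03780 went from 74.4% to 7.48% and from 67.9% to 4.28%. One place on chromosome 2 was lower in every context. It was annotated to the promoter of RAD51C (AT2G45280), a DNA recombination gene, and to an exon and the 3′ UTR of its neighbour GCP1 (AT2G45270). There CHH methylation was 28.8% in Col-0 and 0.148% in rbp-ko-1 over 136 cytosines (18669468 to 18669974), CHG 48.5% and 0.424%, and CG 53.4% and 1.36%. In CHG, an exon of AT1G25180 had 57.7% and 4.18%, and the promoter of UCNL (AT3G20830), a protein kinase gene, had 39.8% and 3.69%. In CHH, the promoter of AT1G21050 had 41.6% and 13.97%, and that of ACA1 (AT1G27770), a calcium-pumping ATPase, had 31.5% and 6.29%.

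Fewer DMRs were higher in rbp-ko-1, and several of those named by the same rule lay among close paralogs. In CG, 1 DMR in the promoter of ABCB24 (AT4G28620) and an exon of its neighbour ABCB23 (AT4G28630), both ABC transporter genes, had 7.01% in Col-0 and 62.2% in rbp-ko-1 (chromosome 4, 14139879 to 14139984). The promoters of AT4G09830 and AT2G04655 went from 11.99% to 59.3% and from 19.8% to 66.7%. In CHG, the promoter region shared by CYCB1;1 (AT4G37490), a mitotic cyclin gene, and AT4G37500 went from 15.4% to 73.0% (chromosome 4, 17624962 to 17625094), and an overlapping CHH DMR went from 2.68% to 16.8%. The promoter region of RPL23A (AT3G04400), a ribosomal protein gene, and AT3G04390 went from 0.517% to 41.7% in CHG (chromosome 3, 1166000 to 1166250) and from 0.396% to 12.4% in an overlapping CHH DMR. Next to each of these, another CHH DMR was lower, at 14.3% and 6.36% by CYCB1;1 and 18.4% and 9.57% by RPL23A. In CHH, an exon and 3′ UTR of AT1G24851 went from 3.41% to 37.7%, the promoter of AT1G58643 from 8.22% to 29.9%, and 1 DMR at RPS2B (AT1G58684) and AT1G58725 from 2.84% to 32.6%. The values at ABCB23, ABCB24 and the AT1G58 genes are uncertain, because near-identical neighbouring copies can share reads.

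Promoters were annotated at most CHH DMRs of the table, which lists only regions annotated to a gene. A DMR can have several features, and of 2909 CG DMRs 2154 had an exon and 1677 a promoter. Promoters were annotated at 4629 of the lower CHH DMRs (81.5%) and 133 of the higher ones (86.4%), a difference that did not pass the Fisher exact test (adjusted p = 0.196). Lower CHH DMRs were more often at transcription start sites, with 648 (11.4%) against 4 higher ones (2.60%, odds ratio 0.207, adjusted exact p = 0.000931), and in exons (38.2% against 24.7%, adjusted p = 0.00278) and introns (19.5% against 10.4%, adjusted p = 0.0124). In 5′ UTRs the shares were 3.42% of lower and 7.14% of higher CHH DMRs (adjusted exact p = 0.0430), and at transcription end sites 10.97% and 4.55% (adjusted p = 0.0189). Lower CHH DMRs were also longer, with a median of 240 bp against 133 bp for higher ones. A longer region can touch more features, and the tests took no account of length. In CG, exons were annotated at 1551 lower DMRs (71.3%) and 603 higher ones (82.0%, odds ratio 1.83, adjusted exact p = 7.04e-08), and promoters at 1321 (60.8%) and 356 (48.4%, odds ratio 0.607, adjusted p = 7.04e-08). Lower CHG DMRs were more often in promoters, 75.4% against 54.9% (odds ratio 0.397, adjusted exact p = 0.0124). For CHG exons the shares were 48.9% and 64.7% (adjusted exact p = 0.0612), a difference that passed without the mitochondrial genome and its chromosome 2 copy (odds ratio 2.25, adjusted p = 0.0390). In the same run other calls were lost. At CG transcription start sites the odds ratio went from 0.484 to 0.763 (adjusted exact p = 0.0290, then 0.660) and at CG end sites from 0.486 to 0.671 (adjusted p = 0.0124, then 0.301). In CG introns it went from 1.33 to 1.26 (adjusted exact p = 0.0124, then 0.0630), and at CHG end sites, with 0 higher DMRs, it was 0 in both, with 38 and 17 lower DMRs (adjusted p = 0.0430, then 0.163).

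Lower CHH and CHG DMRs lay near the centromeres, where transposons and repeats are dense, more often than higher ones. Within 3 Mb of a centromere lay 3261 of 5638 lower nuclear CHH DMRs (57.8%) and 41 of 153 higher ones (26.8%), with an odds ratio of 0.267 (Fisher exact test, adjusted p = 8.64e-14). In CHG the shares were 54.5% of lower and 18.0% of higher DMRs (odds ratio 0.183, adjusted exact p = 1.85e-06). In CG they were 25.01% and 17.7% (odds ratio 0.646, adjusted exact p = 5.00e-05). The CG call was lost without the chromosome 2 copy of the mitochondrial genome (odds ratio 0.837, adjusted exact p = 0.132). At a minimum difference of 20 points the CHG and CHH calls were lost too (adjusted exact p = 0.129 and 0.541), with 15 and 4 higher DMRs left. The odds ratios there, 0.294 and 0, kept their direction, but the CHH value rested on 0 of 4 higher DMRs. Only 3 of 13 lower CHH DMRs of that size (23.1%) and 34 of 74 lower CHG DMRs (45.9%) lay within 3 Mb. The excess of lower CHH DMRs near centromeres thus describes mainly small differences.

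**Figure D3:**
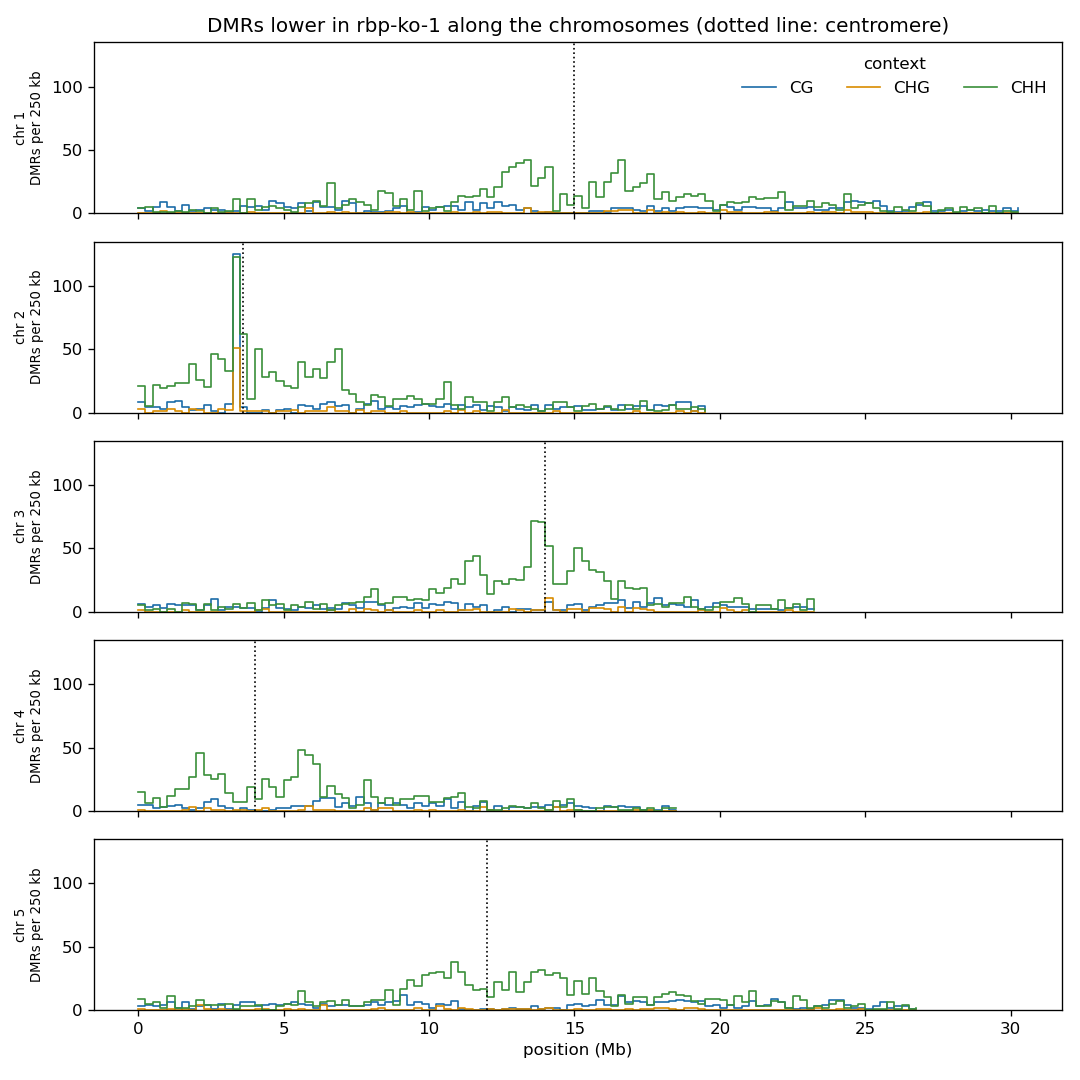
Number of DMRs lower in rbp-ko-1 per 250 kb (vertical axes) along chromosomes 1 to 5 (horizontal axis, position in Mb), with 1 line per context and a dotted line at the centromere. CHH DMRs are dense around the centromeres, where 57.8% lie within 3 Mb. The chromosome 2 copy of the mitochondrial genome holds 134 lower CG and 163 lower CHH DMRs.

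The mitochondrial genome and the large copy of it next to the centromere of chromosome 2 (3.2 to 3.6 Mb) stood apart from the rest. In the mitochondrial genome 285 DMRs were lower and 9 higher, and in the chromosome 2 copy 350 were lower and 7 higher. Together they held 149 of the lower CHG DMRs (35.6%), 281 of the lower CG DMRs (12.9%) and 205 of the lower CHH DMRs (3.61%). Lower mitochondrial DMRs had median levels of 21.0% in Col-0 and 9.28% in rbp-ko-1 in CG, 11.5% and 4.42% in CHG, and 2.96% and 0.574% in CHH. At COX2, a subunit gene of cytochrome c oxidase, the median over 8 lower CG DMRs was 21.6% in Col-0 and 10.3% in rbp-ko-1. At the ribosomal RNA gene RRN26 it was 19.5% and 11.6% over 5. These 2 genes were chosen after their values were seen. Without both places, 1893 CG, 270 CHG and 5475 CHH DMRs were lower and 722, 49 and 153 higher, with shares of lower DMRs of 72.4%, 84.6% and 97.3%.

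CHG DMRs mostly overlapped CHH or CG DMRs, in counts that include the mitochondrial genome and its chromosome 2 copy. These places held 35.6% of the lower CHG DMRs, and the overlap was not run without them. Of the 470 CHG DMRs, 296 (63.0%) overlapped a CHH DMR and 189 (40.2%) a CG DMR, in the same direction in 98.99% and 99.5% of cases. The shares of lower DMRs in each context alone would give 87.1% and 69.4% in the same direction. Random placements gave means of 3.8% and 4.79%. CG and CHH DMRs overlapped less, with 328 of 2909 CG DMRs (11.3%, against 2.95% for random placements) and 93.6% in the same direction, where the shares alone would give 73.4%. The direction was not tested, as all contexts were measured in the same libraries. For each pair of contexts no random placement reached the observed share (permutation p = 0.0099, the smallest 100 placements can give). The placements were not held to annotated genes or to the parts near centromeres where lower CHH and CHG DMRs cluster. The test therefore cannot separate overlap at single places from clustering in the same parts of a chromosome.

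RBP45D itself carried no DMR. The nearest annotated genes with one were AT5G19020 on one side and AT5G19410 on the other. Within 1 Mb either side of RBP45D lay 103 DMRs, and 143 of 220 windows of this size had as many or more (median 132.5). Among the 12 genes of the RBP45 and RBP47 family and the U1 snRNP, 2 carried a DMR, and all 5 of their DMRs were lower. The promoter of RBP47C′ (AT1G47500) had 6.11% CHH methylation in Col-0 and 1.74% in rbp-ko-1 at the longer of its DMRs and 6.45% and 1.89% at the other. U1-70K (AT3G50670), a core protein of the U1 snRNP that acts in splicing, had 11.3% and 3.78% and 7.65% and 2.23% at promoter CHH DMRs and 85.1% and 74.9% at an exonic CG DMR. The list did not pass the test against other genes (odds ratio 0.707, adjusted exact p = 1).

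Of 43 flowering-time genes, 5 carried a DMR, all in CG, with 3 lower and 2 higher. FLC, the floral repressor of the vernalization pathway, FT, the mobile flowering signal, and CO, its activator in long days, carried none. Promoter CG methylation went from 34.1% in Col-0 to 7.87% in rbp-ko-1 at CRY2 (AT1G04400), a blue-light receptor, from 30.8% to 1.16% at FD (AT4G35900), the partner of FT, and from 20.7% to 2.12% at FLD (AT3G10390), a repressor of FLC. These DMRs had 12, 8 and 5 cytosines. TOE1 (AT2G28550), a floral repressor, went from 8.58% to 27.1%, and MAF2 (AT5G65050), a relative of FLC, from 5.95% to 57.7% in a DMR of 4 cytosines over its 5′ UTR, an exon and an intron. The list had a DMR in 11.6% of its genes against 22.1% of other genes (odds ratio 0.465, Fisher exact test, adjusted p = 0.415). None of the 43 genes carried a CHH DMR, against 12.6% of other genes (adjusted exact p = 0.0293). That call was lost against lists matched on gene length (permutation, adjusted p = 0.0516) and with gene bodies only (adjusted p = 1), although the matched lists had a mean of 4.86 genes with a CHH DMR against 0 observed.

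Of 30 genes of RNA-directed DNA methylation, 11 carried a DMR, with 12 DMRs lower and 3 higher. DCL3, the dicer that makes most of the pathway's small RNAs, carried none. CLSY1 (AT3G42670), which recruits RNA polymerase IV, had promoter CHH methylation of 26.1% in Col-0 and 14.9% in rbp-ko-1 at one DMR and 13.8% and 4.11% at another, and exonic CG levels of 76.2% and 59.96%. The promoter of MORC6 (AT1G19100), a silencing ATPase, had 23.3% and 11.4% over 308 CHH cytosines, and that of HEN1 (AT4G20910), a small-RNA methyltransferase, had 10.2% and 2.09%. SUVH2 (AT2G33290), which helps recruit RNA polymerase V, had 5.15% and 1.13% in CHH. In CG, NRPD1, the largest subunit of RNA polymerase IV, had one DMR lower (72.9% and 47.0%) and one higher (52.1% and 80.6%), as did RDR2, the RNA polymerase that copies its transcripts (77.5% and 62.0%, 68.3% and 86.8%). DRD1 (32.7% and 12.01%), CLSY2 (16.7% and 1.31%), the argonaute gene AGO6 (12.8% and 1.27%) and the methyltransferase gene DRM1 (6.40% and 1.24%) were lower in CG, and DCL1 was higher (79.6% and 91.1%). The AGO6 DMR had only 5 cytosines. The list did not pass the Fisher exact test in all contexts together (36.7% against 22.0% of other genes, odds ratio 2.05, adjusted p = 0.415) or in CG (odds ratio 2.72, adjusted p = 0.120). With gene bodies only the CG list passed (odds ratio 3.89, adjusted exact p = 0.0296), and at 20 points or more it did not (adjusted p = 0.899). These genes are long, with a median of 5012.5 bp against 2078 bp, and no call held against random lists matched on gene length (permutation, adjusted p = 0.790 in all contexts, 0.625 in CG and 0.537 in CG with gene bodies only). The matched lists had means of 7.77, 5.08 and 3.94 genes with a DMR, against 11, 8 and 7 observed.

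The remaining lists were small and none passed the Fisher exact test in the main run, which took genes and promoters together. Of 18 genes that maintain or remove methylation, 3 carried a DMR (odds ratio 0.707, adjusted exact p = 0.934). Promoter CHH methylation went from 22.0% in Col-0 to 33.2% in rbp-ko-1 at VIM1 (AT1G57820) and from 19.2% to 7.68% at VIM3 (AT5G39550), both cofactors of CG maintenance, and exonic CG methylation went from 3.73% to 23.1% at SUVH5 (AT2G35160), a histone methyltransferase. The SUVH5 DMR had only 5 cytosines. ROS1, MET1, CMT2 and CMT3 carried no DMR. Of 14 heat-response genes, 4 carried a DMR (odds ratio 1.41, adjusted exact p = 0.788). The heat-shock factor genes HSFA1D (49.2% and 19.1%) and HSFA1B (9.68% and 1.41%) and the chaperone gene HSP101 (9.89% and 0.955%) were lower in exonic CG, HSFA1D was also lower in promoter CHH (21.3% and 12.1%), and HSP90.1 was higher in exonic CG (1.26% and 8.51%). The exonic CG DMRs of HSFA1D, HSFA1B and HSP101 had only 5, 5 and 7 cytosines, and that of HSP90.1 had 15. With gene bodies only the heat list passed in CG (odds ratio 5.10, adjusted exact p = 0.0466, against 0.220 with promoters and 0.899 at 20 points or more), but not against lists matched on gene length (permutation, adjusted p = 0.226 with gene bodies only and 0.625 with promoters). Those matched lists had a mean of 1.10 genes with a DMR in the gene body against 4 observed, and the median length of the heat genes, 2072 bp, was close to the 2078 bp of all genes.

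Genes known to be silenced by methylation or imprinted carried lower DMRs at 4 of the 11 members with an annotated protein-coding gene (odds ratio 2.02, Fisher exact test, adjusted p = 0.548). FWA (AT4G25530), whose promoter repeats are a classic target of RNA-directed methylation, had 14.98% CHH methylation in Col-0 and 6.497% in rbp-ko-1 over its promoter, 5′ UTR, an exon and an intron (chromosome 4, 13038208 to 13038647). The promoter of SDC (AT2G17690), a repeat-containing target of the same pathway, had 61.0% and 22.2% CG methylation over 4 cytosines. The promoter of SUP (AT3G23130) had 5.73% and 1.23% in CHH. The promoter of QQS (AT3G30720), which is flanked by transposon remnants, had 9.56% and 3.66% over 404 CHH cytosines (chromosome 3, 12346648 to 12347897) and 6.18% and 1.81% at another DMR.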

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

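The run without the mitochondrial genome and its chromosome 2 copy, and the length-matched lists, were chosen after the results were seen, and the other alternatives were planned. No alternative turned the excess of lower DMRs into an excess of higher ones in any context, although CHH was even at 30 points. At least 20 points of difference left 978 lower and 442 higher CG, 82 and 15 CHG, and 13 and 4 CHH DMRs, and at least 30 points left 419 and 194, 12 and 8, and 1 and 1. Lower shares were then 60% in CHG (exact 95% interval 36.1 to 80.9%, adjusted p = 0.755) and 50% in CHH (adjusted p = 1). At least 10 cytosines left 1266 lower and 355 higher CG and 27 higher CHG DMRs, and at least 100 bp left 1115 and 279 CG and 255 and 27 CHG. The 50% with the larger area statistic held 1168 and 286 CG, 210 and 25 CHG, and 2903 and 14 CHH. Without the mitochondrial genome and its copy 270 lower CHG DMRs were left. By total length, 80.0% of CG, 91.9% of CHG and 99.2% of CHH was lower.

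The larger size of higher CHH differences shrank to 0.585 points at 10 cytosines or more (adjusted permutation p = 0.0509), against 0.0484 without the mitochondrial genome and its copy, and was 0.130 points between means weighted by length. Such means gave 4.73 points in CHG. In CHG the higher minus lower size, which passed in none of the runs, turned to -0.80 points in that run (adjusted permutation p = 0.566). There the CHG exon odds ratio was 2.25 (adjusted exact p = 0.0390) and the CG centromere odds ratio 0.837 (adjusted p = 0.132, against 0.000183 within 2 Mb and 0.00134 at 20 points). At 20 points the centromere odds ratios were 0.294 in CHG (adjusted exact p = 0.129) and 0 in CHH (adjusted p = 0.541), with 15 and 4 higher DMRs. Of the lower CHH DMRs left there, 3 of 13 (23.1%) lay within 3 Mb, against 57.8% in the main run. The cause of these changes was not tested. Overlap between contexts and the window around RBP45D kept their direction. Of 56 DMRs of named genes, 26 remained at 20 points, 16 at 30 points and 43 at 10 cytosines.

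No paired analysis was possible because the table holds no values per library. For the same reason the replicate block, leaving out each library, the coverage minimum and other splits of the samples were not run. The reannotation with promoters of 2 kb or 1 kb was not run, because the gene table used here has no strand. The 50% feature overlap, planned with it, was not run either. Unknown depth limits each level, most of all in DMRs of few cytosines.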

Other observations

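The groups and tests in this part were chosen after the results were seen. Some repeated genes outside the fixed lists carried many CHH DMRs. Genes of 5S ribosomal RNA, which lie in tandem arrays, carried 239 DMRs, 186 of them on chromosome 3. Of these, 225 were lower in CHH, with median levels of 11.5% in Col-0 and 4.22% in rbp-ko-1, and 1 was higher. As copies of 5S genes are near-identical, reads cannot always be assigned to single copies. Genes picked by a description that names transposons or reverse transcriptase carried 141 DMRs at 52 genes, of which 122 were lower and 0 higher in CHH, with medians of 9.19% and 3.47%. Their gene type was not checked, and the mitochondrial genome and its chromosome 2 copy were not left out. Whether either group carried more DMRs than other genes was not tested, and 97.4% of all CHH DMRs were lower.

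MicroRNA genes more often carried a lower CHH DMR in the gene or promoter than protein-coding genes did, 64 of 326 (19.6%) against 11.7% (odds ratio 1.84, Fisher exact test, adjusted p = 8.45e-05). The share was 13.6% among long non-coding RNA genes (odds ratio 1.19, adjusted exact p = 0.00206), 6.56% among tRNA genes (odds ratio 0.529, adjusted p = 7.44e-05) and 7.67% among snoRNA genes (odds ratio 0.626, adjusted p = 0.0332). In CG, all 4 classes carried lower DMRs less often than protein-coding genes, of which 8.57% did. The shares were 4.60% of microRNA genes (odds ratio 0.515, adjusted exact p = 0.0104), 5.46% of long non-coding RNA genes (odds ratio 0.616, adjusted p = 3.98e-10), 3.36% of tRNA genes (odds ratio 0.371, adjusted p = 1.62e-06) and 3.14% of snoRNA genes (odds ratio 0.345, adjusted p = 0.000628). These tests took no account of gene length or position.

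The lower DMRs of the mitochondrial genome and its chromosome 2 copy raise the question of where the methylated reads came from. A uniform gap in bisulfite conversion would add about the same number of points in every context, but 87.8% of lower mitochondrial CG DMRs dropped by more than 5.95 points, the largest CHH drop there. Only called regions enter this comparison, with a median of 23 cytosines in CG and 72 in CHH. With the calling thresholds unknown, the calling itself may have favoured larger drops in CG, so the comparison does not decide. One dilution factor for every context stays open: the median CHH ratio of rbp-ko-1 to Col-0 was 0.408 times the CG ratio, but lower nuclear CHH DMRs of like Col-0 level also had low ratios, with a median of 0.249 over 1380 against 0.205 in the mitochondrial genome. The copy held 134 lower CG DMRs while the highest of 1189 other windows of 400 kb held 19. Reads shared with the mitochondrial genome and a loss in the nuclear copy itself, where the median CG ratio was 0.597, would both give this and cannot be told apart, because levels cannot be assigned to either copy.

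The lower CHH methylation at nuclear DMRs, taken without the chromosome 2 copy, had a median drop of 5.93 points. A uniform conversion gap of that size would put every Col-0 level above it. Yet 1361 of 5587 CHH DMRs of either direction with 10 or more cytosines had a lower Col-0 level, so a uniform gap of that size is not the cause. A smaller one could add to the drop. Among the 153 higher CHH DMRs the lower quartile of the Col-0 level was 1.09%, which argues against a uniform gap larger than that at those regions. The loss, as the authors called it, was also not restricted to short regions. Of 5439 lower DMRs with 10 or more cytosines, 543 (9.98%, exact 95% interval 9.20 to 10.8%) were 1 kb or longer. A growth or library batch shared by the libraries of a genotype cannot be told apart from the mutation, as 0 columns hold values per library, and both may contribute.

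The split of nuclear CG DMRs by level, again without the chromosome 2 copy, depended on how it was made. By the Col-0 level alone, 641 DMRs under 20% were lower and 269 higher (70.4% lower), and at 20% or more 1252 were lower and 453 higher (73.4% lower), a difference that did not pass the Fisher exact test (odds ratio 0.862, p = 0.108). By the rbp-ko-1 level alone, 1383 under 20% were lower and 82 higher (94.4% lower), and at 20% or more 510 were lower and 640 higher (44.3% lower, odds ratio 21.2, Fisher exact test, p = 8.37e-191). By both levels, 88.7% were lower where both genotypes were under 20%, 53.0% where both were at 20% or more and 79.9% where they lay on either side. Each of these levels is one end of the change itself, so the change helps to set the classes in every split and the tests do not show that losses depend on level.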
